A study of Mus musculus with 30 samples.

How the data were processed

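RNA of 30 mouse livers was sequenced in 10 groups of 3 libraries, 5 groups per sex: control, 2,4-BPS, BPSIP, BPS and E2. Per the labels, each library was made from the RNA of a single liver at 10 weeks of age, and the offspring of a group came at random from litters of different dams. The authors aligned reads with HISAT2 and counted them per gene with HTSeq, and their notes also name DESeq2 and R 3.2.0. The versions of the other tools, the genome build, the annotation and the strand setting are not given in the sources used here. The authors deposited a table of counts and a table of FPKM over the same gene symbols. The deposited FPKM equal the deposited counts divided by the library's sum of counts and by a single length per gene, with a largest relative deviation of 3.46e-06, so the FPKM carry no further scaling. All 30 libraries entered, and no gene name was left unread.

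Libraries held 29711711 to 37719069 counts. Levels are given as CPM, counts scaled by the library total over the kept genes times its TMM factor from the fit of 30 libraries (below). By the total alone, 1 count in the smallest library is 0.0337 CPM. A total of 3 counts over a group, 0.101 CPM at that depth, served as the floor for groups without counts. Against a group at 0 a fold is given as at least N-fold, and with 1 to 3 counts as a ratio with its 95% counting interval. These bounds cover counting error alone. Members of the Mup, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Sult2a, Sult3a, Saa and Hspa1 clusters are alike in sequence, so reads may be shared among neighbours and their single values carry that uncertainty.

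Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups as design, 13874 in females, 13474 in males and 14131 in the fit of both sexes. TMM factors (0.928 to 1.12) scaled the libraries, a robust quasi-likelihood model was fitted (glmQLFit), and contrasts were tested with glmQLFTest. The common biological coefficient of variation was 0.0915, 0.0873 and 0.0899. P values were adjusted by Benjamini and Hochberg over the genes of a fit, and 0.05 was the threshold. The 15 libraries of a sex shared a fit for exposures against control, for pairs of exposures and for the joint test of 4 exposures. All 30 libraries shared a fit for the female minus male difference of each exposure effect and for the sexes among controls. Values in brackets are log2 fold changes ± standard error of the fit, and ± beside CPM is the standard deviation over 3 libraries. P values measure the spread between the 3 libraries of a group. Comparisons against the same controls share the chance values of these controls.

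Gene lists, 36 in all, were written from general knowledge of mouse liver before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists with at least 5 tested members entered camera (limma 3.58.1) with a preset correlation of 0.01 between genes, and again with an estimated one. This gave 33 lists in females and 34 in males. A list is described by the members that pass over all genes and by those that pass when adjusted over the list alone. Its camera p (preset correlation) is adjusted over lists, of which other splits called up to 20. As a further alternative, fry's PValue tests whether a set's genes move, on balance, one way, and PValue.Mixed whether they change in either direction; neither compares the set with other genes or sets. Genes were named by rule. Per exposure the rule takes the 5 largest changes each way among genes that pass, with a mean of at least 1 CPM and no overlap between the groups, without predicted models, clones and pseudogenes. It adds members of lists that were called, with smallest p first, a panel of 12 genes fixed beforehand, and the 3 largest changes each way for pairs of exposures and for sex differences. It also takes the 8 smallest p per sex in the joint test and the sex-linked genes. The text prints the 2 members with smallest p of lists called with both correlations.

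The score of liver sex is the mean log2 CPM (2 counts added) of the 29 listed male-biased genes minus that of the 39 female-biased genes, compared by exact permutation of 6 libraries, two-sided. Correlations of log2 fold changes were set beside 20 simulated data sets per sex without any exposure effect. GENCODE M21 on GRCm38 was used only to tell which genes are Y-linked. After the data were examined a mixed comparison was added: each exposed male library was mixed with the female control library of the same number at the share of female RNA estimated from Y-linked genes, and then compared with the libraries labelled male control. Another alternative added then compares each exposed male group with the mean of the other 3. Alternatives planned beforehand were DESeq2 1.42.0, RLE factors, no filter, the replicate number as a block, leaving out each library in turn, fits of 6 or of all 30 libraries, a minimum log2 fold change of 1, the estimated correlation, fry, and limma on log2 FPKM with 1 or 0.1 added. Other splits of the same libraries were fitted in the same way.

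The fits were tested on simulated data made from these counts, in which 200 genes were changed by folds of up to 4. Some items are not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.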

Results

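Liver RNA was sequenced from 10 week old offspring of ICR mice, an outbred stock, whose dams had received a bisphenol compound or estradiol in drinking water through pregnancy and lactation. Bisphenol S (BPS) carries 2 phenol rings joined by a sulfone group and is used in place of bisphenol A. In 2,4-BPS, its positional isomer, the hydroxyl group of 1 ring is moved, and BPSIP is a BPS in which 1 hydroxyl group carries an isopropyl ether. Estradiol (E2) is the main endogenous oestrogen and served as the reference hormone. According to the labels, 8 dams per group drank water with 10 ng/mL of a compound and 0.001% ethanol, adjusted to 5 µg per kg of body weight per day, for about 40 days, and control dams drank the ethanol alone. Each of the 10 groups held 3 libraries, described as livers of offspring from different dams.

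The sex labels were examined first, because the liver is among the organs whose transcripts differ most between sexes. The 4 Y-linked genes measured above background (Ddx3y, Eif2s3y, Kdm5d and Uty) summed to at most 0.543 CPM in any library labelled female and to between 138 ± 8.19 and 168 ± 1 CPM (mean ± SD, n = 3) in the exposed male groups. In the libraries labelled male control the sum was 88.4 ± 5.98 CPM, lower in 3 of 3 libraries than in every exposed male library. These 3 libraries also held transcripts of genes that the exposed males nearly lacked. A1bg, a female-specific liver gene, stood at 1470 CPM against 2540 in control females and 2.92 in exposed males, and Cyp2b9, a female-specific cytochrome P450, at 195 against 563 and 0.654 CPM. Over 25 female-specific genes the median level was 0.449 of that in control females (quartiles 0.342 and 0.624). The library label is therefore written out below for this group. Only the 4 male exposure comparisons with it were repeated with exposed males mixed with 41.8% of female control libraries, the share from Y-linked genes. This is called the mixed comparison.

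**Figure D1:**
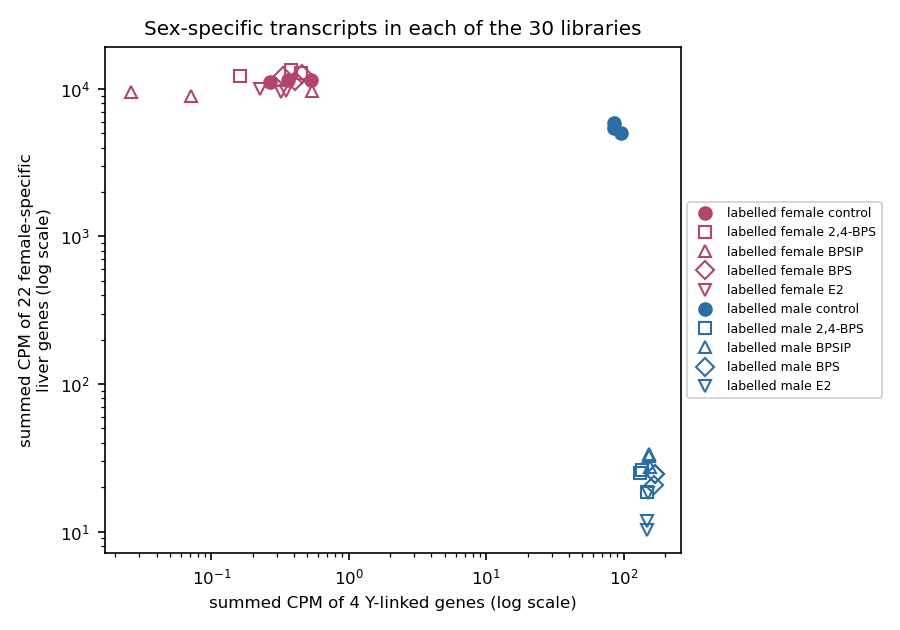
Summed CPM of 4 Y-linked genes (x axis) against summed CPM of 22 members of the female-biased list (y axis), 1 point per library, 30 libraries, symbols by exposure and colours by sex. The libraries labelled male control lie between the females and the exposed males, with a Y-linked sum of 88.4 ± 5.98 CPM (mean ± SD, n = 3).

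The comparison of control libraries asked which genes differ between the sexes without exposure. Of 14131 genes, 2068 were higher and 2199 lower in females than in the libraries labelled male control. Ddx3y, a Y-linked RNA helicase, had 0.168 ± 0.126 against 44.5 ± 1.98 CPM (log2 fold change −8.03 ± 0.19, n = 3 per group). Of the male-biased list, 27 of 29 were lower and 0 were higher, the same adjusted over the list alone (adjusted p = 1.87e-174), among them the oxysterol hydroxylase gene Cyp7b1 (−3.42 ± 0.06), the selenium-binding protein gene Selenbp2 (−2.20 ± 0.05) and the complement gene C8a (−2.14 ± 0.05). Of the female-biased list, 35 of 39 were higher and 1 was lower, the same over the list alone (adjusted p = 1.55e-55). Among them were Cyp4a14 (2.49 ± 0.06), a fatty acid hydroxylase, Hao2 (1.55 ± 0.07) and Rtn4 (1.24 ± 0.06). Fatty acid oxidation and PPAR alpha targets were higher as a list (25 of 39 were higher and 8 were lower, the same over the list alone, adjusted p = 1.68e-18), as were neutrophil markers (13 of 14 were higher and 0 were lower, the same over the list alone, adjusted p = 3.3e-05). Xist, which marks the inactive X chromosome, is not among the genes listed in the tables.

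Exposure to 2,4-BPS was compared with control in females to ask which liver transcripts the isomer leaves changed at 10 weeks. Acute phase genes rose and fatty acid oxidation genes fell. Lcn2, which encodes the siderophore-binding protein lipocalin 2, rose from 36.2 ± 2.26 to 223 ± 16.7 CPM (log2 fold change 2.63 ± 0.06, n = 3 per group, in what follows ± is the standard error for log2 fold changes and the SD for CPM). Saa1, a serum amyloid A gene, rose from 40.2 ± 1.83 to 160 ± 11.9 CPM (2.00 ± 0.07). Ehhadh, an enzyme of peroxisomal beta-oxidation, fell from 1080 ± 8.99 to 375 ± 3.36 CPM (−1.52 ± 0.05). Of 13874 genes tested, 1513 rose and 1168 fell.

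Of the acute phase list, 29 of 39 rose and 3 fell, the same over the list alone (adjusted p = 8.48e-59). Interferon response genes rose with them (29 of 37 rose and 2 fell, 30 and 2 over the list alone, adjusted p = 1.67e-30), among them the interferon-inducible GTPase gene Igtp (1.36 ± 0.06). Of antigen presentation genes, 16 of 20 rose and 1 fell, 17 and 1 over the list alone (adjusted p = 2.13e-25). Among them were the class II chain gene H2-Ab1 (1.11 ± 0.06) and the invariant chain gene Cd74 (0.89 ± 0.06). Markers of macrophages and Kupffer cells moved the same way (17 of 26 rose and 0 fell, 19 and 0 over the list alone, adjusted p = 9.35e-14). Examples are the scavenger receptor gene Marco (1.16 ± 0.07) and the perforin-like gene Mpeg1 (0.91 ± 0.05). In cholesterol biosynthesis, 19 of 25 rose and 1 fell, the same over the list alone (adjusted p = 1.26e-19), including Hmgcs1 (0.69 ± 0.05) and Cyp51 (0.75 ± 0.06). Of fatty acid oxidation and PPAR alpha targets, 24 of 39 fell and 7 rose, 25 and 7 over the list alone (adjusted p = 9.35e-14). They included the pantetheinase gene Vnn1 (−1.30 ± 0.07) and Cyp4a14 (−0.44 ± 0.06) beside Ehhadh. Of cell cycle genes, 9 of 36 rose and 0 fell, 10 and 0 over the list alone (adjusted p = 0.000971); the member with the smallest p, Cdkn1a (2.11 ± 0.12), encodes an inhibitor of cyclin-dependent kinases, while Mki67 (1.02 ± 0.16) marks proliferating cells.

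Among single genes, the phosphodiesterase gene Gdpd3 (8.3 ± 1.58 against 0.245 ± 0.0987 CPM, 5.07 ± 0.28) and Igsf23 (4.08 ± 0.29) rose most, and Esr1, the oestrogen receptor alpha gene, rose as well (1.40 ± 0.13), as did Cyp2b10 (0.56 ± 0.09) and Cyp7a1 (0.26 ± 0.06), the rate-limiting enzyme of bile acid synthesis. The lipoprotein receptor gene Vldlr (−2.64 ± 0.13), the activin-binding protein gene Fst (−2.86 ± 0.35), Psmc3ip (−4.15 ± 0.49), Cyp4a12a (−2.44 ± 0.26), the clock repressor gene Nr1d1 (−0.73 ± 0.07) and Cyp1a2 (−0.19 ± 0.05) fell. The muscle genes Acta1 (2.78 ± 0.82) and Tnnt3 (2.73 ± 0.68), Dmbt1 (−4.61 ± 1.44) and the gluconeogenic gene Pck1 (−0.14 ± 0.05) passed in the fit of 15 libraries but not in every alternative. In a fit of the 6 libraries alone the adjusted p was 0.16 for Acta1, 0.108 for Tnnt3 and 0.165 for Dmbt1, and with the replicate block 0.0709 for Acta1. With a library left out, Acta1 had 0.125 and 0.126 without control libraries 1 and 2 and 0.14 and 0.0535 without 2,4-BPS libraries 1 and 2, and Tnnt3 0.318 without 2,4-BPS library 1. Dmbt1 had 0.249 without control library 2 and 0.145, 0.077 and 0.139 without 2,4-BPS libraries 1, 2 and 3, and Pck1 0.148, 0.139 and 0.051 without control libraries 1, 2 and 3 and 0.172 and 0.0982 without 2,4-BPS libraries 1 and 3. In this comparison 15 of 33 gene lists were called and 7 of these calls held with an estimated correlation, while the other 8 had an adjusted p of 0.256 to 0.774 with an estimated correlation. Splits of the same 6 libraries that ignore the exposure called up to 17 lists and 0 genes.

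BPSIP changed more genes in females than any of the other 3 exposures, 2690 upward and 2664 downward of 13874. Genes of cholesterol synthesis rose and genes of glucose metabolism and insulin signalling fell. The squalene epoxidase gene Sqle rose from 25.9 ± 2.4 to 186 ± 9.25 CPM (2.85 ± 0.07, n = 3 per group). Igfbp1, an insulin-repressed gene for a binding protein of insulin-like growth factors, fell from 77.5 ± 3.29 to 7.11 ± 0.696 CPM (−3.45 ± 0.07). G6pc, the phosphatase of the last step of glucose release, fell from 368 ± 10.1 to 67.7 ± 5.96 CPM (−2.45 ± 0.06).

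In cholesterol biosynthesis, 23 of 25 rose and 0 fell, the same over the list alone (adjusted p = 1.28e-107), Hmgcs1 among them (2.70 ± 0.06). Of glucose metabolism and insulin signalling genes, 27 of 31 fell and 2 rose, the same over the list alone (adjusted p = 2.23e-22), Pck1 included (−1.24 ± 0.05). Of fatty acid oxidation and PPAR alpha targets, 33 of 39 fell and 2 rose, 34 and 3 over the list alone (adjusted p = 2.25e-29). Among them were the lipoprotein lipase inhibitor gene Angptl4 (−2.39 ± 0.07), the acyl-CoA thioesterase gene Acot1 (−2.59 ± 0.07) and Cyp4a14 (−1.30 ± 0.06). Interferon response genes rose (31 of 37 rose and 0 fell, the same over the list alone, adjusted p = 9.04e-48), such as Igtp (2.75 ± 0.06). Antigen presentation genes rose too (17 of 20 rose and 1 fell, 17 and 2 over the list alone, adjusted p = 1.54e-30). Examples are H2-Aa (2.08 ± 0.06) and Cd74 (1.84 ± 0.06). So did macrophage markers (21 of 26 rose and 0 fell, the same over the list alone, adjusted p = 2.42e-17). They included Marco (2.03 ± 0.07) and Mpeg1 (1.21 ± 0.05). Acute phase genes rose (23 of 39 rose and 4 fell, 23 and 5 over the list alone, adjusted p = 1.24e-10). Members include Lcn2 (2.26 ± 0.06), Saa2 (1.93 ± 0.07) and Saa1 (1.67 ± 0.07). In the endoplasmic reticulum stress list, 21 of 30 rose and 3 fell, the same over the list alone (adjusted p = 2.52e-18). Among them were the chaperone gene Hyou1 (2.10 ± 0.06) and Manf (1.99 ± 0.06). In the heat shock list, 15 of 19 rose and 0 fell, the same over the list alone (adjusted p = 8.67e-13). Examples are the chaperone genes Hsp90aa1 (1.40 ± 0.06) and Hsph1 (1.30 ± 0.06).

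The genes raised most were Ly6i (3.84 ± 0.39 against 0.088 ± 0.0319 CPM, 5.40 ± 0.55), Gdpd3 (5.32 ± 0.28), the inducible nitric oxide synthase gene Nos2 (5.29 ± 0.62), H2-M2 (5.28 ± 0.42) and the ubiquitin-like gene Ubd (5.09 ± 0.30). Those lowered most were the glycogen-targeting phosphatase subunit gene Ppp1r3g (−5.61 ± 0.23), the G protein regulator gene Rgs16 (−4.82 ± 0.07), the pheromone-binding protein gene Mup15 (−4.35 ± 0.41), the NADPH oxidase gene Nox4 (−4.11 ± 0.35) and Krt23 (−3.64 ± 0.25). Fasn, the fatty acid synthase gene (1.08 ± 0.06), Esr1 (0.64 ± 0.13) and Cyp7a1 (0.43 ± 0.06) rose, while Nr1d1 (−1.29 ± 0.08), Cyp2b10 (−0.35 ± 0.09) and Cyp1a2 (−0.30 ± 0.05) fell. Mup15 varied widely among control libraries (663 ± 404 CPM), and it belongs to a gene family with shared sequence. For this exposure 19 of 33 gene lists were called and 9 of these calls held with an estimated correlation, while the other 10 had an adjusted p of 0.0733 to 0.797 with an estimated correlation.

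In females exposed to BPS, 1293 of 13874 genes rose and 1040 fell against control. Cdkn1a rose 9.22-fold, from 3.09 ± 0.596 to 28.4 ± 2.25 CPM (n = 3 per group), and the PPAR alpha target Cyp4a14 rose 4.37-fold, from 229 ± 1.58 to 994 ± 33.9 CPM (2.13 ± 0.06). Cyp4a12b, a male-biased fatty acid hydroxylase gene, fell from 15 ± 2.29 to 0.0948 ± 0.066 CPM (−7.21 ± 0.30).

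Cholesterol biosynthesis genes rose (22 of 25 rose and 0 fell, the same over the list alone, adjusted p = 1.11e-53), among them Hmgcs1 (1.28 ± 0.05) and Sqle (1.36 ± 0.07). In the heat shock list, 13 of 19 rose and 0 fell, 14 and 0 over the list alone (adjusted p = 1.91e-26). Among them were Hsph1 (1.26 ± 0.06) and the inducible chaperone genes Hspa1a (2.55 ± 0.28) and Hspa1b (2.37 ± 0.13), which share most of their sequence. Acute phase genes rose as well (21 of 39 rose and 2 fell, 23 and 3 over the list alone, adjusted p = 1.39e-13). Examples are Saa2 (1.17 ± 0.07), Lcn2 (1.10 ± 0.06) and Saa1 (0.92 ± 0.07). Of interferon response genes, 31 of 37 rose and 0 fell, 33 and 1 over the list alone (adjusted p = 4.29e-32). They included Igtp (0.93 ± 0.06) and the regulator gene Irf7 (0.75 ± 0.06). Endoplasmic reticulum stress genes included the chaperones Dnajb9 (1.00 ± 0.06) and Manf (0.88 ± 0.06) (16 of 30 rose and 0 fell, 20 and 0 over the list alone, adjusted p = 3.5e-16). Of immediate early genes, 11 of 25 rose and 1 fell, 13 and 1 over the list alone (adjusted p = 3.45e-07); the 2 with the smallest p, the antiproliferative gene Btg2 (2.37-fold) and the stress-inducible gene Gadd45g (1.16 ± 0.10), both restrain growth.

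The calpain gene Capn3 (2.81 ± 0.44) and the dipeptidase gene Dpep1 (2.79 ± 0.34) also rose. Cd300ld4 (−4.75 ± 0.66), Fst (−2.89 ± 0.35), Pianp (−2.38 ± 0.25) and the histone gene H2bc8 (−2.21 ± 0.22) fell. Cyp7a1 (0.69 ± 0.06), Esr1 (0.74 ± 0.13) and Fasn (0.49 ± 0.06) rose, and Nr1d1 (−0.51 ± 0.07) and Cyp2b10 (−0.41 ± 0.10) fell. Pck1 (0.14 ± 0.05) and Cyp1a2 (−0.18 ± 0.05) did not pass in every alternative: the adjusted p of Pck1 was 0.0512 with RLE factors, 0.0806, 0.0884 and 0.201 without control libraries 1, 2 and 3 and 0.17 and 0.132 without BPS libraries 2 and 3, and that of Cyp1a2 was 0.0603 without control library 1 and 0.0824 without BPS library 1. Under BPS 19 of 33 gene lists were called and 6 of these calls held with an estimated correlation, while the other 13 had an adjusted p of 0.0858 to 0.83 with an estimated correlation.

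E2 was included as the reference oestrogen, and in females 1445 genes rose and 1467 fell of 13874. Lipogenic genes fell: Thrsp, a regulator of lipogenesis, from 671 ± 1.01 to 52.5 ± 2.85 CPM (−3.68 ± 0.06, n = 3 per group), and the stearoyl-CoA desaturase gene Scd1 from 2200 ± 15.3 to 751 ± 14 CPM (−1.56 ± 0.06). Dbp, a transcription factor gene under direct control of the circadian clock, fell from 105 ± 1.1 to 10.9 ± 1.11 CPM (−3.28 ± 0.08). Cyp4a14 rose 7.96-fold, from 229 ± 1.58 to 1830 ± 83.4 CPM (2.99 ± 0.06).

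Of the fatty acid and triglyceride synthesis list, 21 of 29 fell and 2 rose, 23 and 4 over the list alone (adjusted p = 2.83e-33), Fasn among those that fell (−0.56 ± 0.06). In the circadian clock list, 18 of 27 fell and 7 rose, the same over the list alone (adjusted p = 1.6e-28). Among them were Usp2 (−2.06 ± 0.09) and Nr1d1 (−0.99 ± 0.07). Male-biased genes fell (14 of 28 fell and 1 rose, 18 and 1 over the list alone, adjusted p = 2.67e-17), including the steroid dehydrogenase gene Hsd3b5 (−1.85 ± 0.08), Cyp4a12a (−4.49 ± 0.31) and Cyp4a12b, whose ratio of control to E2 was 546 (counting interval 187 to 2650, with 1 to 3 counts in the E2 group). Cholesterol biosynthesis genes rose (16 of 25 rose and 2 fell, 18 and 2 over the list alone, adjusted p = 6.37e-24). Examples are Hmgcs1 (1.61 ± 0.05) and Msmo1 (1.21 ± 0.06). Interferon response genes rose (18 of 37 rose and 3 fell, 23 and 4 over the list alone, adjusted p = 1.63e-17). They included the GTPase genes Igtp (1.80 ± 0.06) and Ifi47 (1.55 ± 0.08). Of immediate early genes, 9 of 25 rose and 2 fell, 11 and 2 over the list alone (adjusted p = 8.93e-07). Members include the growth regulator gene Myc (2.03 ± 0.12) and Gadd45g (1.58 ± 0.10).

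Cdkn1a (3.72 ± 0.12), Capn3 (3.93 ± 0.43), Igsf23 (3.45 ± 0.29) and Slc4a1 (2.79 ± 0.26), the anion exchanger of red cells, were among the genes raised most. Camk2b (−4.92 ± 0.24) and Mup15 (−4.21 ± 0.41) were lowered, and Havcr1 had a control to E2 ratio of 84.8 (counting interval 28.7 to 414). Cyp2b10 (−1.97 ± 0.10), Cyp1a2 (−1.27 ± 0.05) and Saa1 (−0.40 ± 0.07) fell and Cyp7a1 rose (0.39 ± 0.06). Pck1 (0.14 ± 0.05) passed with all libraries, but its adjusted p was 0.0652, 0.0737 and 0.173 without control libraries 1, 2 and 3 and 0.088 without E2 library 3. After E2, 20 of 33 gene lists were called and 6 of these calls held with an estimated correlation, while the other 14 had an adjusted p of 0.11 to 0.669 with an estimated correlation. For adipose markers, 1 of these, the test pointed down (adjusted p = 0.0472, and 0.335 with an estimated correlation) while the median log2 fold change was 0.23 and the mean 0.10. Its adjusted p was 0.0503 with RLE factors, 0.0598 and 0.194 without control libraries 2 and 3 and 0.102 and 0.204 without E2 libraries 1 and 3.

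**Figure D2:**
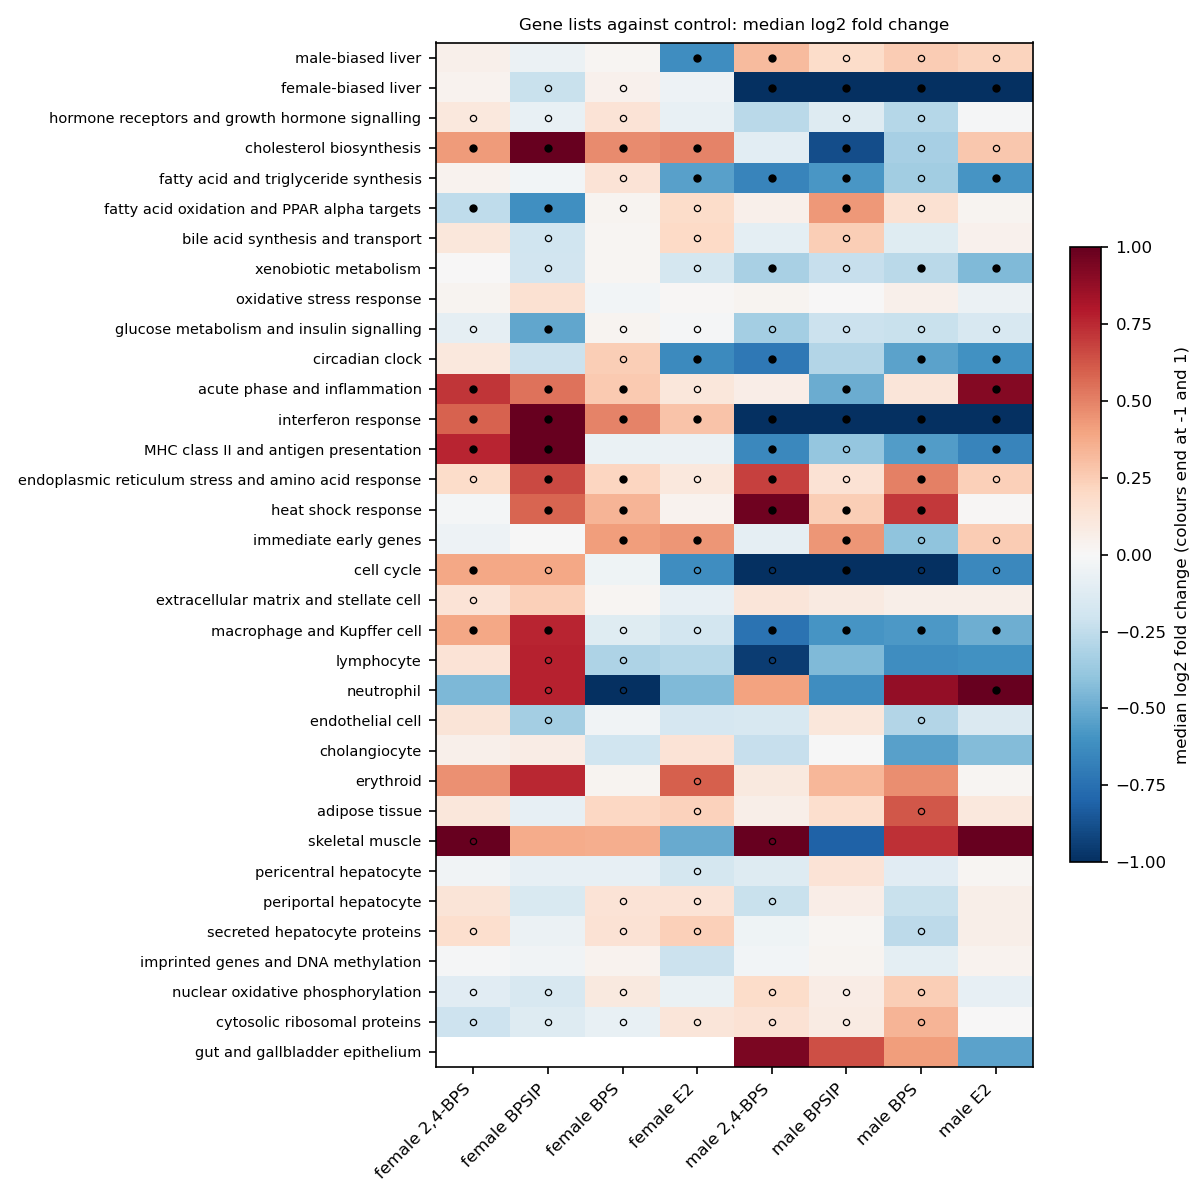
Gene lists (vertical) in the 8 comparisons of exposed with control libraries (horizontal), coloured by the median log2 fold change of the list's tested members, with colours ending at −1 and 1. Filled dots mark lists called with both correlations and open dots those called with the preset correlation only; cholesterol biosynthesis is raised in the 4 female comparisons and interferon response is lowered in the 4 male ones.

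**Figure D3:**
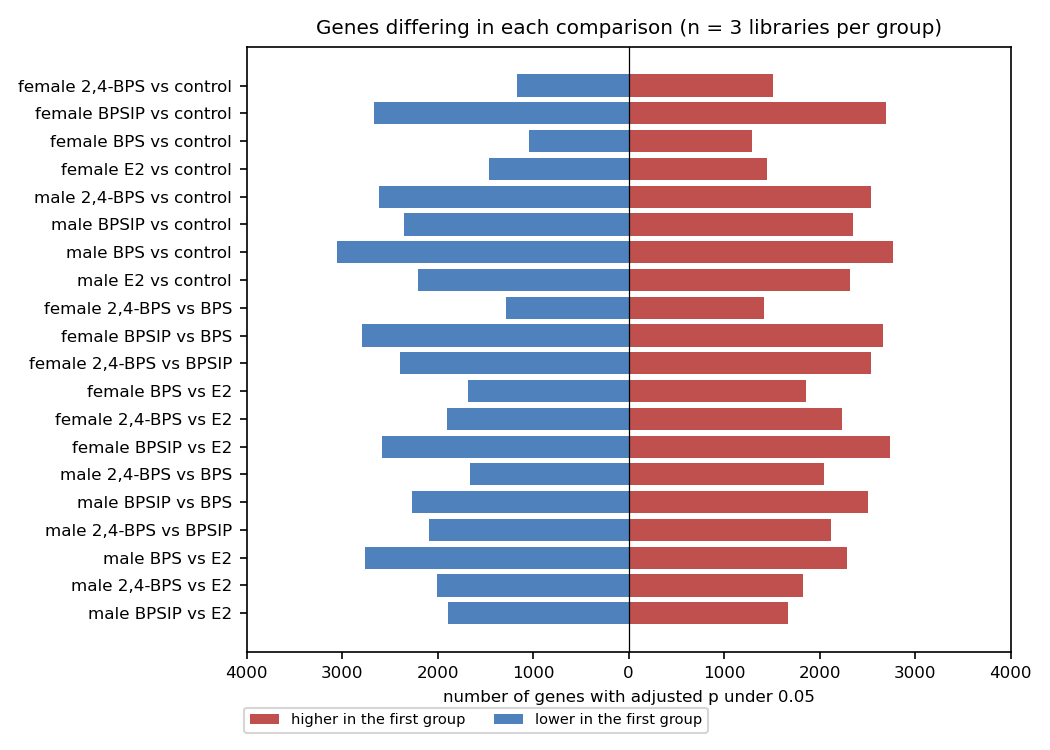
Number of genes higher and lower (bars, x axis, counts of genes with an adjusted p under 0.05) in each comparison (y axis), n = 3 libraries per group. Of the 4 female comparisons with control, BPSIP has the longest bars, 2690 genes higher and 2664 lower.

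The 4 male comparisons are against the libraries labelled male control, and the value of the mixed comparison stands beside each gene; for a list, the mixed adjusted p follows, preceded by the mixed counts where a single exposure is described. Values in this paragraph are in the order 2,4-BPS, BPSIP, BPS and E2. Interferon response genes fell with every exposure: 34, 35, 33 and 35 of 37 fell and 1, 1, 1 and 1 rose, 35, 35, 33 and 36 down against 2, 1, 1 and 1 up over the list alone (adjusted p = 9.22e-27, 3.93e-31, 6.03e-16 and 1.32e-27, mixed 8.71e-23, 2.96e-24, 1.25e-15 and 9.95e-23, all downward). Irf7, a regulator of interferon genes, changed by log2 values of −1.91 ± 0.07, −1.74 ± 0.07, −1.67 ± 0.07 and −1.31 ± 0.07 (mixed −1.42, −1.34, −1.30 and −1.12, n = 3 per group). Of macrophage markers, 19, 18, 20 and 20 of 26 fell and 0, 2, 1 and 2 rose, 19, 18, 20 and 20 down against 0, 2, 2 and 3 up over the list alone (adjusted p = 9.1e-14, 4.91e-09, 2.16e-08 and 3.03e-07, mixed 0.000326, 0.0182, 0.0126 and 0.0722, all downward). Mpeg1, a pore-forming protein gene of phagocytes, changed by −1.55 ± 0.05, −1.45 ± 0.05 and −0.67 ± 0.05 with 2,4-BPS, BPSIP and E2 (mixed −1.07, −1.04 and −0.67), and with BPS from 193 ± 6.95 to 97.4 ± 3.46 CPM (mixed −0.84). The female-biased list fell in each (33, 32, 33 and 34 of 38 fell and 2, 3, 3 and 2 rose, 34, 33, 33 and 34 down against 2, 3, 3 and 2 up over the list alone, adjusted p = 1.98e-63, 5.91e-53, 1.18e-48 and 2.22e-63), but pointed upward in each mixed comparison (0.12, 0.00613, 0.0607 and 0.0444). Cyp2b9 shows this, with −7.60 ± 0.21, −8.56 ± 0.23, −8.12 ± 0.22 and −8.91 ± 0.24 against a mixed 0.31, 0.32, 0.28 and 0.34. Nr1d1 changed by 1.43 ± 0.06, 1.86 ± 0.06, 1.05 ± 0.06 and 1.19 ± 0.06 (mixed 1.26, 1.53, 1.03 and 1.10) and Cyp2b10 by −0.86 ± 0.14, −2.71 ± 0.16, −2.51 ± 0.16 and −3.11 ± 0.17 (mixed −0.35, −0.75, −0.75 and −0.81).

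With 2,4-BPS, chaperone genes rose in males. Hspb1, a small heat shock protein gene, rose from 5.22 ± 1.02 to 117 ± 5.41 CPM (4.49 ± 0.10, mixed 3.66 ± 0.10, n = 3 per group), and Hspa5, the main chaperone of the endoplasmic reticulum, from 441 ± 6.07 to 1970 ± 38.8 CPM (2.16 ± 0.04, mixed 1.53 ± 0.03). Of the heat shock list, 18 of 19 rose and 0 fell, the same over the list alone (adjusted p = 5.54e-40, mixed 18 and 0, 6.78e-31), Hsph1 and Hspa1a among them (2.04 ± 0.05 and 3.09 ± 0.11, mixed 1.39 and 2.26). Of the endoplasmic reticulum stress list, 23 of 30 rose and 1 fell, 24 and 1 over the list alone (adjusted p = 1.62e-25, mixed 15 and 4, 4.78e-15), with Manf (2.59 ± 0.05, mixed 1.91). Genes of lipid synthesis fell (22 of 28 fell and 4 rose, the same over the list alone, adjusted p = 4.32e-15, mixed 16 and 6 of 29 tested, 3.58e-05). Among them were the acetyl-CoA carboxylase gene Acacb (−1.57 ± 0.06, mixed −0.97), Scd1 (−1.06 ± 0.04, mixed −0.07) and Fasn (−0.92 ± 0.10, mixed −0.25). Of clock genes, 20 of 27 fell and 6 rose, the same over the list alone (adjusted p = 7.14e-10, mixed 20 and 5, 2.84e-11), with Dbp (−1.61 ± 0.06, mixed −0.68). Xenobiotic metabolism genes fell (27 of 47 fell and 7 rose, 29 and 7 over the list alone, adjusted p = 1.12e-06, mixed 27 and 8, 2.87e-08). Examples are Sult1a1 (−0.98 ± 0.05, mixed −0.21) and Cyp2c37 (−1.43 ± 0.05, mixed 0.56). Antigen presentation genes fell too (16 of 20 fell and 0 rose, the same over the list alone, adjusted p = 1.5e-08, mixed 9 and 4, 0.112). They included H2-T23 (−0.85 ± 0.05, mixed −0.17) and H2-K1 (−0.72 ± 0.05, mixed −0.41). Male-biased genes rose (20 of 29 rose and 2 fell, the same over the list alone, adjusted p = 1.16e-08). Members include Selenbp2 (1.58 ± 0.04, mixed 0.82) and Hsd3b5 (1.26 ± 0.05, mixed 0.56). This list pointed down in the mixed comparison (adjusted p = 0.0213).

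Of 13474 genes, 2540 rose and 2611 fell with 2,4-BPS, and 3650 of these 5151 calls (70.9%) kept call and direction in the mixed comparison. Cyp4a14 (2.38 ± 0.05, mixed 2.42), Fam171b (3.50 ± 0.16, mixed 2.71), H2bc8 (3.04 ± 0.26, mixed 2.61), Acta1 (3.17 ± 0.51, mixed 2.56) and Saa1 (1.34 ± 0.06, mixed 0.67) rose. Gbp10 (−2.24 ± 0.11, mixed −0.87), Cd5l (−1.09 ± 0.04, mixed −0.44), Esr1 (−0.73 ± 0.11, mixed −0.48), Cyp1a2 (−0.46 ± 0.04, mixed −0.62) and Cyp7a1 (−0.36 ± 0.05, mixed 0.20) fell. Losses among female-biased genes were much larger than in the mixed comparison: Sult3a1 (−8.69 ± 0.12, mixed −1.22), Sult3a2 (−9.03 ± 0.28, mixed −1.05), Cyp2b13 (−9.04 ± 0.18, mixed −0.88) and Slc22a26 (−8.84 ± 0.15, mixed −0.52), and Hsd3b1, without counts under 2,4-BPS, was at least 124-fold lower (floor of 3 counts over the group, mixed log2 −0.37). Mup20 (1.02 ± 0.28, mixed 0.19) had an adjusted p of 0.0577 without control library 3 and 0.0505 without 2,4-BPS library 1. Here 17 of 34 gene lists were called and 10 of these calls held with an estimated correlation, while the other 7 had an adjusted p of 0.0548 to 0.499 with an estimated correlation.

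Males exposed to BPSIP had 2350 genes higher and 2350 lower, of 13474, and 3373 of these 4700 calls (71.8%) kept call and direction in the mixed comparison. Fatty acid oxidation genes rose: Cyp4a14 from 40.7 ± 3.03 to 1370 ± 56.1 CPM (5.08 ± 0.06, mixed 4.42 ± 0.04, n = 3 per group) and Ehhadh from 363 ± 7.56 to 1100 ± 64.4 CPM (1.61 ± 0.04, mixed 1.58 ± 0.03). Fdps, an enzyme of cholesterol synthesis, fell from 110 ± 8.74 to 30.3 ± 2.11 CPM (−1.85 ± 0.06, mixed −1.03 ± 0.05). Lbp, whose product binds bacterial lipopolysaccharide, fell from 355 ± 10.6 to 136 ± 3.77 CPM (−1.37 ± 0.05, mixed −1.29 ± 0.03).

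Of fatty acid oxidation and PPAR alpha targets, 30 of 39 rose and 5 fell, 30 and 6 over the list alone (adjusted p = 8.18e-23, mixed 30 and 4, 6.07e-29). Cholesterol biosynthesis genes fell (23 of 25 fell and 0 rose, 24 and 0 over the list alone, adjusted p = 1.59e-34, mixed 23 and 0, 2.69e-28), with Cyp51 (−1.52 ± 0.05, mixed −0.91). Of lipid synthesis genes, 19 of 28 fell and 5 rose, 19 and 6 over the list alone (adjusted p = 6.7e-13, mixed 18 and 6 of 29 tested, 0.000417). Among them were Scd1 (−1.82 ± 0.04, mixed −0.24), the acetyl-CoA synthetase gene Acss2 (−1.46 ± 0.06, mixed −1.14) and Fasn (−1.56 ± 0.10, mixed −0.43). Acute phase genes fell (23 of 38 fell and 1 rose, 24 and 2 over the list alone, adjusted p = 1.48e-13, mixed 25 and 3, 2.13e-15), Saa4 (−1.31 ± 0.04, mixed −1.26) and Saa1 (−1.33 ± 0.06, mixed −1.33) included. Of the heat shock list, 12 of 19 rose and 2 fell, the same over the list alone (adjusted p = 2.23e-08, mixed 10 and 2, 0.00129). Examples are Hspa1b (1.59 ± 0.08, mixed 0.83) and Hspb1 (1.89 ± 0.11, mixed 1.20). Immediate early genes rose (12 of 24 rose and 3 fell, the same over the list alone, adjusted p = 7.03e-05, mixed 12 and 3, 0.00167). They included Fos (4.66 ± 0.42, mixed 3.86) and Jun (1.72 ± 0.08, mixed 1.10), while Myc fell (−1.72 ± 0.11, mixed −1.73). Of cell cycle genes, 18 of 35 fell and 0 rose, 21 and 0 over the list alone (adjusted p = 0.000119, mixed 13 and 1, 0.0258); the cyclin gene Ccnd1 (−1.84 ± 0.09, mixed 0.41) turned its direction there and the ribonucleotide reductase gene Rrm2 (−2.06 ± 0.28, mixed −0.97) kept it.

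Cfap53 (5.94 ± 0.47, mixed 5.16), Meig1 (4.64 ± 0.66, mixed 3.85), Fam171b (4.17 ± 0.16, mixed 3.42), Cyp7a1 (0.69 ± 0.05, mixed 0.70) and Pck1 (0.32 ± 0.03, mixed −0.02) rose with BPSIP. Gbp10 (−2.32 ± 0.11, mixed −0.88), Clec4f (−0.68 ± 0.05, mixed −0.25), Esr1 (−1.01 ± 0.12, mixed −0.58) and Cyp1a2 (−0.65 ± 0.04, mixed −0.75) fell. Among female-biased genes, Sult2a5 had no counts and was at least 394-fold lower (mixed 0.51). The ratio of control to BPSIP was 1380 for Slc22a27 (counting interval 247 to 54500, mixed −0.20) and 756 for Sult2a6 (135 to 29900, mixed 0.73). Cyp2b13 (−10.64 ± 0.21, mixed −0.89), Cyp3a16 (−8.93 ± 0.15, mixed 0.09) and Sult3a1 (−8.73 ± 0.12, mixed −1.22) fell too. In BPSIP males 19 of 34 gene lists were called and 10 of these calls held with an estimated correlation, while the other 9 had an adjusted p of 0.0709 to 0.804 with an estimated correlation.

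BPS changed 2769 genes upward and 3052 downward of 13474, the most of the 4 male comparisons without a limit on the fold, but the fewest (726) at a log2 fold change of at least 1. Of the 5821 calls without a limit, 4365 (75%) kept call and direction in the mixed comparison. Cyp4a14 rose from 40.7 ± 3.03 to 1290 ± 41.6 CPM (4.97 ± 0.06, mixed 4.34 ± 0.04, n = 3 per group), and Cidec, a lipid droplet protein gene, from 2.54 ± 0.262 to 28.8 ± 1.91 CPM (3.49 ± 0.16, mixed 2.80 ± 0.14). Cyp3a13, a drug-metabolizing P450, fell from 253 ± 9.59 to 89 ± 5.12 CPM (−1.52 ± 0.05, mixed −1.30 ± 0.04), and Cyp1a2 from 836 ± 25.1 to 397 ± 8.45 CPM (−1.09 ± 0.04, mixed −0.98 ± 0.03).

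Heat shock genes rose (17 of 19 rose and 0 fell, the same over the list alone, adjusted p = 1.8e-18, mixed 16 and 0, 6.07e-11). Among them were Hsp90aa1 (1.64 ± 0.05, mixed 1.14) and Hspa1b (1.52 ± 0.08, mixed 0.84). Of the endoplasmic reticulum stress list, 18 of 30 rose and 6 fell, the same over the list alone (adjusted p = 1.47e-08, mixed 15 and 7, 0.00392). Examples are Manf (1.56 ± 0.05, mixed 1.06) and Hspa5 (1.16 ± 0.04, mixed 0.74). Antigen presentation genes fell (17 of 20 fell and 0 rose, the same over the list alone, adjusted p = 4.44e-08, mixed 10 and 4, 0.0966). They included H2-D1 (−0.88 ± 0.04, mixed −0.26) and H2-T23 (−0.87 ± 0.05, mixed −0.19). Of xenobiotic metabolism genes, 27 of 47 fell and 10 rose, the same over the list alone (adjusted p = 7.04e-08, mixed 32 and 7, 3.97e-08), with Cyp2c37 (−2.12 ± 0.05, mixed 0.47) beside Cyp3a13. Clock genes fell (19 of 27 fell and 6 rose, the same over the list alone, adjusted p = 1.23e-05, mixed 19 and 5, 1.14e-07). Transcripts of ribosomal proteins (57 of 64 rose and 2 fell, 59 and 2 over the list alone, adjusted p = 3.06e-17, and 0.146 with an estimated correlation, mixed 61 and 2, 6.35e-22) and nuclear oxidative phosphorylation proteins (39 of 44 rose and 1 fell, the same over the list alone, adjusted p = 6.72e-09, and 0.146 with an estimated correlation, mixed 33 and 1, 0.000125) were higher by count.

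Ubd (3.81 ± 0.37, mixed 3.08), Rsph9 (3.51 ± 0.50, mixed 2.83), Tuba8 (3.50 ± 0.49, mixed 3.17), Cyp7a1 (0.58 ± 0.05, mixed 0.64) and Saa1 (1.18 ± 0.06, mixed 0.55) rose with BPS. Gbp10 (−2.04 ± 0.10, mixed −0.85), Cd5l (−0.76 ± 0.04, mixed −0.33), Esr1 (−0.88 ± 0.12, mixed −0.55) and Pck1 (−0.40 ± 0.03, mixed −0.49) fell. Among female-biased genes the ratio of control to BPS was 3700 for Sult3a2 (counting interval 664 to 146000, mixed −1.06), and Cyp2b13 (−10.04 ± 0.20, mixed −0.93), Sult3a1 (−9.59 ± 0.13, mixed −1.29) and Slc22a26 (−9.41 ± 0.16, mixed −0.57) fell. Fasn (−0.32 ± 0.10, mixed −0.02) had an adjusted p of 0.0558 and 0.0639 without control libraries 1 and 3. With BPS 21 of 34 gene lists were called and 8 of these calls held with an estimated correlation, while the other 13 had an adjusted p of 0.0502 to 0.483 with an estimated correlation.

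In males exposed to E2, the acute phase genes Saa1, Saa2, Orm2 and Lcn2 had their highest means of the 10 groups. Saa2 rose from 32.1 ± 3.86 to 6790 ± 368 CPM (7.74 ± 0.12, mixed 6.87 ± 0.10, n = 3 per group), Saa1 from 98.3 ± 4.44 to 8040 ± 216 CPM (6.37 ± 0.07, mixed 5.50 ± 0.07), and Orm2, an acid glycoprotein gene, from 18.7 ± 1.48 to 1090 ± 80.8 CPM (5.88 ± 0.14, mixed 5.04 ± 0.10). Lcn2 rose from 43.4 ± 2.17 to 1120 ± 91.1 CPM (4.70 ± 0.19, mixed 3.87 ± 0.12). Of 13474 genes, 2323 rose and 2210 fell, and 3197 of these 4533 calls (70.5%) kept call and direction in the mixed comparison.

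Of the acute phase list, 28 of 38 rose and 5 fell, 29 and 6 over the list alone (adjusted p = 1.21e-28, mixed 23 and 7, 1.28e-18). Among them were Orm1 (2.09 ± 0.04, mixed 1.44) and the pentraxin gene Apcs (2.07 ± 0.05, mixed 1.54). Neutrophil markers rose (12 of 13 rose and 0 fell, the same over the list alone, adjusted p = 9.6e-07, mixed 14 and 0 of 14 tested, 5.65e-11); the pair with the smallest p, Lcn2 and Il1b (2.31 ± 0.22, mixed 1.89), also stand in the acute phase list. Antigen presentation genes fell (15 of 20 fell and 1 rose, the same over the list alone, adjusted p = 7.25e-10, mixed 8 and 3, 0.145). Examples are B2m (−0.49 ± 0.03, mixed −0.39) and Cd74 (−1.23 ± 0.05, mixed 0.03). Of lipid synthesis genes, 20 of 28 fell and 5 rose, the same over the list alone (adjusted p = 1.08e-11, mixed 17 and 7 of 29 tested, 0.00173); Scd1 (−1.72 ± 0.04, mixed −0.21) fell, and Insig2 (1.64 ± 0.05, mixed 1.15), whose product restrains lipid synthesis, rose. Xenobiotic metabolism genes fell (31 of 47 fell and 7 rose, 31 and 8 over the list alone, adjusted p = 5.13e-12, mixed 32 and 8, 5.65e-11). They included Sult1a1 (−1.63 ± 0.05, mixed −0.40) and Cyp2c37 (−2.03 ± 0.05, mixed 0.52). Of clock genes, 16 of 27 fell and 6 rose, 17 and 6 over the list alone (adjusted p = 5.16e-10, mixed 20 and 6, 9.44e-11). Members include Dbp (−2.64 ± 0.07, mixed −0.88) and Tef (−1.35 ± 0.05, mixed −0.78).

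The hormone gene Cck (5.12 ± 0.67, mixed 4.37), the muscle gene Myom2 (4.94 ± 0.46, mixed 4.15) and Cyp4a14 (4.14 ± 0.06, mixed 3.60) rose with E2. Cd163 (−2.51 ± 0.14, mixed −1.16), Cyp7a1 (−1.44 ± 0.05, mixed −0.11), Mup20 (−1.09 ± 0.28, mixed −1.94), Fasn (−0.86 ± 0.10, mixed −0.23) and Cyp1a2 (−0.49 ± 0.04, mixed −0.65) fell. The ratio of control to E2 was 2960 for Cyp2b13 (counting interval 1010 to 14400, mixed −0.86), and Sult3a1 (−10.77 ± 0.14, mixed −1.21), Cyp2a4 (−10.50 ± 0.20, mixed −0.12), A1bg (−9.99 ± 0.24, mixed −0.39) and Cyp3a16 (−9.76 ± 0.16, mixed 0.11) fell. In E2 males 15 of 34 gene lists were called and 9 of these calls held with an estimated correlation, while the other 6 had an adjusted p of 0.059 to 0.172 with an estimated correlation.

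**Figure D4:**
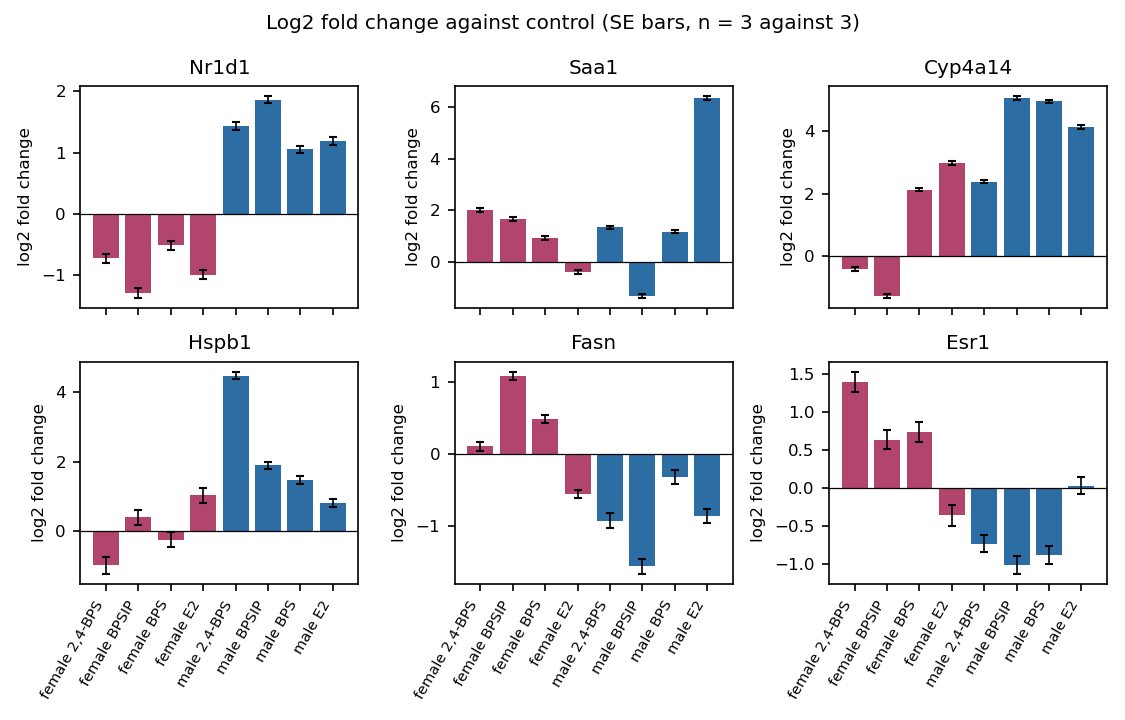
Log2 fold change against control (y axis) of Nr1d1, Saa1, Cyp4a14, Hspb1, Fasn and Esr1 in the 8 comparisons (x axis), as bars with the standard error of the fit, n = 3 libraries per group. Saa1 reaches 6.37 ± 0.07 in E2 males, and Nr1d1 is lowered in the 4 female groups and raised in the 4 male groups.

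Compound pairs were compared at the same stated dose. Litter or genotype was not tested. In females, 2,4-BPS and BPS differed at 2701 genes (1420 higher, 1281 lower), n = 3 per group. Gdpd3 (8.3 ± 1.58 against 0.0665 ± 0.0392 CPM, 6.86 ± 0.35), Trim12a (ratio 387, counting interval 69.2 to 15300) and Cyp4a12b (5.77 ± 0.33) were higher with 2,4-BPS. The complement factor H related gene Cfhr3 (−4.57 ± 0.33), the signal recognition gene Srp54a (−4.34 ± 0.43) and the clock activator gene Npas2 (−3.43 ± 0.54) were lower. Macrophage markers were higher with 2,4-BPS (22 of 26 up and 0 down, 24 and 0 over the list alone, adjusted p = 7.77e-28) and heat shock genes lower (16 of 19 down and 0 up, the same over the list alone, adjusted p = 2.73e-23). BPSIP and BPS differed at 5455 genes (2664 higher, 2791 lower). The innate receptor gene Clec4e (6.53 ± 0.51), Gdpd3 (7.11 ± 0.35) and Trim12a (ratio 669, counting interval 120 to 26500) were higher with BPSIP, and the glycogen regulator gene Ppp1r3g (−4.89 ± 0.24), Igfbp1 (−4.78 ± 0.07) and Rgs16 (−3.82 ± 0.07) lower. Cholesterol biosynthesis genes were higher (23 of 25 up and 0 down, 23 and 1 over the list alone, adjusted p = 1.65e-46) and fatty acid oxidation genes lower (37 of 39 down and 1 up, the same over the list alone, adjusted p = 4.53e-41) with BPSIP. Between 2,4-BPS and BPSIP, 4931 genes (2536 higher, 2395 lower) differed: the potassium channel gene Kcnj16 (5.36 ± 0.48), Igsf23 (4.24 ± 0.29) and Ppp1r3g (4.14 ± 0.24) were higher with 2,4-BPS, and Cfhr3 (−6.17 ± 0.31), Srp54a (−4.79 ± 0.42) and Chil1 (−4.63 ± 0.40) lower. Cholesterol biosynthesis genes were lower with 2,4-BPS than with BPSIP (23 of 25 down and 0 up, 24 and 0 over the list alone, adjusted p = 3.37e-77).

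Against E2, BPS females differed at 3548 genes (1862 higher, 1686 lower), 2,4-BPS females at 4141 genes (2239 higher, 1902 lower) and BPSIP females at 5323 genes (2738 higher, 2585 lower). With BPS, Thrsp (4.49 ± 0.06), the clock repressor gene Ciart (4.41 ± 0.15) and Havcr1 (ratio 73.8, counting interval 24.9 to 361) were higher than with E2, and Tnfaip8l3 (−3.14 ± 0.49), Fst (−3.12 ± 0.35) and H2bc8 (−2.85 ± 0.22) lower. Clock genes (21 of 27 up and 1 down, the same over the list alone, adjusted p = 7.91e-41) and lipid synthesis genes (23 of 29 up and 3 down, 24 and 3 over the list alone, adjusted p = 1.67e-52) were higher with BPS. With 2,4-BPS, Trim12a (at least 137-fold), Cyp4a12b (ratio 199, counting interval 67.8 to 968) and Havcr1 (ratio 80.9, counting interval 27.4 to 395) were higher than with E2, and Cfhr3 (−5.29 ± 0.32), Srp54a (−4.84 ± 0.42) and the prostaglandin receptor gene Ptger3 (−4.44 ± 0.55) lower. Cell cycle genes were higher with 2,4-BPS (25 of 36 up and 1 down, 28 and 1 over the list alone, adjusted p = 4.94e-05). With BPSIP, Trim12a (at least 237-fold), Ly6i (ratio 418, counting interval 74.7 to 16600) and Cyp4a12b (ratio 336, counting interval 115 to 1630) were higher than with E2, and the adrenergic receptor gene Adra2a (ratio 108, counting interval 36.6 to 526), Igfbp1 (−4.71 ± 0.07) and Cyp4a14 (−4.29 ± 0.07) lower. Antigen presentation genes were higher with BPSIP (17 of 20 up and 1 down, the same over the list alone, adjusted p = 1.29e-28). In the order given, 8 of 19, 11 of 21, 9 of 20, 4 of 16, 9 of 15 and 12 of 23 list calls held with an estimated correlation. Between 2,4-BPS and BPS, the female-biased list had a median log2 fold change of 0.00511 and a mean of −0.197, with a downward test (adjusted p = 4.05e-05, and 0.223 with an estimated correlation).

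Pairs of exposed male groups do not involve the libraries labelled male control. Between 2,4-BPS and BPS, 3710 genes (2048 higher, 1662 lower) differed in males, n = 3 per group. The steroid-metabolizing P450 gene Cyp2g1 (3.49 ± 0.45), Psmc3ip (3.58 ± 0.39) and Ube2u (3.42 ± 0.44) were higher with 2,4-BPS, and Ubd (−4.36 ± 0.39), Cidec (−3.65 ± 0.16) and Hapln1 (−3.62 ± 0.68) lower. Heat shock genes were higher with 2,4-BPS (15 of 19 up and 1 down, the same over the list alone, adjusted p = 2.76e-16). BPSIP and BPS differed at 4767 genes (2502 higher, 2265 lower). Fos (5.04 ± 0.43), Zfp982 (5.11 ± 0.63) and Cfap53 (at least 202-fold) were higher with BPSIP, and Srp54a (ratio 90.8, counting interval 30.7 to 443), Hapln1 (−4.89 ± 0.77) and the nicotinamide methyltransferase gene Nnmt (−4.27 ± 0.10) lower. Endothelial markers were higher with BPSIP (14 of 22 up and 0 down, 15 and 0 over the list alone, adjusted p = 2.7e-07). Between 2,4-BPS and BPSIP, 4213 genes (2124 higher, 2089 lower) differed. The steroid reductase gene Srd5a2 (4.92 ± 0.43), Moxd1 (4.03 ± 0.10) and Tnnt3 (4.38 ± 0.72) were higher with 2,4-BPS, and Cfap53 (−5.94 ± 0.46), Ncapg (−5.93 ± 0.58) and Fos (−4.25 ± 0.40) lower. Cholesterol biosynthesis genes were higher (23 of 25 up and 1 down, the same over the list alone, adjusted p = 3.04e-38) and fatty acid oxidation genes lower (33 of 39 down and 2 up, the same over the list alone, adjusted p = 4.54e-31) with 2,4-BPS than with BPSIP.

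Against E2 in males, BPS differed at 5048 genes (2284 higher, 2764 lower), 2,4-BPS at 3830 genes (1826 higher, 2004 lower) and BPSIP at 3561 genes (1666 higher, 1895 lower). The melanocortin receptor accessory gene Mrap2 (ratio 73.3, counting interval 24.8 to 358), Igsf23 (4.53 ± 0.66) and Ubd (4.27 ± 0.39) were higher with BPS than with E2, and Saa2 (−6.65 ± 0.12), Tnr (−5.70 ± 0.45) and Cfap53 (at least 73.7-fold) lower. Cyp2a5 (5.40 ± 0.08), Cyp2g1 (4.88 ± 0.53) and the major urinary protein gene Mup1 (3.87 ± 0.43) were higher with 2,4-BPS than with E2, and Saa2 (−7.04 ± 0.12), Orm2 (−6.32 ± 0.15) and Lcn2 (−5.60 ± 0.20) lower. Ncapg (3.88 ± 0.49), Fam107a (3.61 ± 0.15) and Fos (3.40 ± 0.37) were higher with BPSIP than with E2, and Saa2 (−9.26 ± 0.13), Saa1 (−7.69 ± 0.07) and Lcn2 (−7.97 ± 0.24) lower. Acute phase genes were lower than with E2 in each: 30, 33 and 32 of 38 were lower and 1, 1 and 1 higher, 31, 34 and 34 down against 1, 1 and 2 up over the list alone (adjusted p = 1.4e-45, 1.25e-48 and 6.97e-75 for BPS, 2,4-BPS and BPSIP). Cholesterol biosynthesis genes were also lower with BPSIP than with E2 (25 of 25 down and 0 up, the same over the list alone, adjusted p = 1.09e-63). In the order given, 3 of 18, 8 of 16, 8 of 14, 5 of 16, 4 of 13 and 8 of 11 list calls held with an estimated correlation.

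Effects were tested as female minus male over 14131 genes, n = 3 per group. All 4 share control females (interferon sum 1440 CPM, lowest of females) and libraries labelled male control (1760 CPM, highest of males). With 2,4-BPS 4919 genes differed, BPSIP 5136, BPS 4362 and E2 2389. Interferon response genes had higher values in females than in males for every exposure: 35, 37, 36 and 35 of 37 higher and 0, 0, 1 and 0 lower, the same over the list alone (adjusted p = 3.18e-45, 1.54e-66, 6.07e-37 and 9.92e-64). For 2,4-BPS, heat shock genes were lower in this sense (18 of 19 down and 0 up, the same over the list alone, adjusted p = 8.54e-27), Hspb1 by −5.50 ± 0.23 and the histone gene H2bc8 by −4.08 ± 0.34. For BPSIP, cholesterol biosynthesis genes were higher (25 of 25 up and 0 down, the same over the list alone, adjusted p = 1.24e-118) and fatty acid oxidation genes lower (36 of 39 down and 3 up, the same over the list alone, adjusted p = 2.84e-53), the latter with Cyp4a14 (−6.37 ± 0.09) and the fasting hormone gene Fgf21 (−5.27 ± 0.33). For BPS, clock genes (18 of 27 up and 1 down, 18 and 3 over the list alone, adjusted p = 7.91e-07) and cholesterol biosynthesis genes (24 of 25 up and 0 down, the same over the list alone, adjusted p = 9.43e-26) were higher, and Cyp4a12b (−7.48 ± 0.27) lower. For E2, acute phase genes were lower (25 of 39 down and 5 up, 26 and 5 over the list alone, adjusted p = 3.86e-41), Saa2 by −8.11 ± 0.12, and so was Myom2 (−6.96 ± 0.89).

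Female-biased genes, which fell against the libraries labelled male control, had positive differences for every exposure: 33, 31, 32 and 34 of 39 higher and 3, 5, 4 and 3 lower, 33, 31, 34 and 35 up against 4, 5, 4 and 3 down over the list alone. Slc22a26 had 9.43 ± 0.17 for 2,4-BPS, Sult3a2 9.66 ± 0.20 for 2,4-BPS and 11.10 ± 0.19 for E2, Sult3a1 10.58 ± 0.13 for BPS and 12.30 ± 0.14 for E2, and Cyp2b13 10.53 ± 0.24 for BPSIP and 10.30 ± 0.22 for BPS. Several of these genes are near 0 counts in exposed males, as is Cyp4a12b in BPS females, so the fitted values depend on the count added before taking logs. No value is given here for genes with at most 3 counts in an exposed group. Hsd3b1 with 2,4-BPS and Sult2a5 with BPSIP had none in males. In the order of exposures, 10 of 21, 8 of 18, 9 of 19 and 6 of 12 list calls held with an estimated correlation.

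Tested jointly over the 4 exposures, 8122 of 13874 genes (58.5%) changed in females and 8605 of 13474 (63.9%) in males, n = 3 per group. In the order control, 2,4-BPS, BPSIP, BPS and E2, Cyp4a14 averaged 229 ± 1.58, 169 ± 9.91, 93.5 ± 8.39, 994 ± 33.9 and 1830 ± 83.4 CPM in females. The metallothionein gene Mt2 averaged 304 ± 16.8, 377 ± 16.3, 25.1 ± 2.25, 241 ± 3.48 and 351 ± 28.7 CPM in females and 660 ± 6.78, 191 ± 11.2, 124 ± 7.57, 174 ± 2.69 and 494 ± 16.5 CPM in males. In males, the betaine methyltransferase gene Bhmt averaged 2590 ± 45.3, 7710 ± 78.5, 2530 ± 6.96, 6990 ± 123 and 5880 ± 88.1 CPM, and Orm1 900 ± 40.1, 1080 ± 22.4, 659 ± 6.5, 1020 ± 21.5 and 3790 ± 157 CPM.

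**Figure D5:**
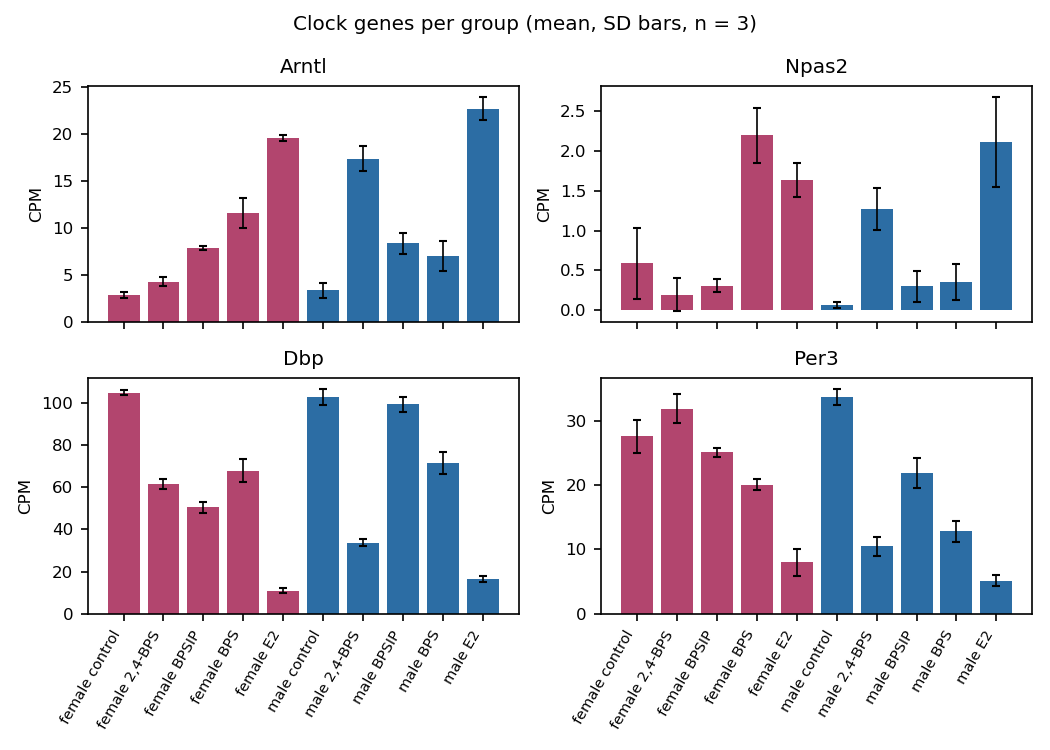
Mean and standard deviation of CPM (y axis) of the clock genes Arntl, Npas2, Dbp and Per3 in the 10 groups (x axis), n = 3 libraries per group. E2 females, 2,4-BPS males and E2 males have the 3 highest means of Arntl and the 3 lowest of Dbp and Per3.

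The score of liver sex averaged −2.02 ± 0.083 (mean ± SD) in control females and 2.28 ± 0.17 in the libraries labelled male control. In females it averaged −2.14 ± 0.073 with 2,4-BPS, −2.09 ± 0.1 with BPSIP, −2.51 ± 0.044 with BPS and −2.96 ± 0.029 with E2. The differences from control were −0.118 (exact permutation p = 0.2, n = 3 per group), −0.0721 (exact permutation p = 0.5), −0.488 and −0.936 (exact permutation p = 0.1 each). In exposed males it averaged 7.5 ± 0.19, 7.17 ± 0.08, 7.49 ± 0.029 and 7.76 ± 0.27, differences of 5.22, 4.88, 5.21 and 5.48 (exact permutation p = 0.1 each). The libraries labelled male control had a female-biased list mean of 5.53, exposed males at most 0.918. No mixed score was made. With 3 libraries per group 0.1 is the smallest exact permutation p, and over 8 tests the adjusted p was 0.229, 0.5 and otherwise 0.133.

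How far the exposures changed the same genes was measured by correlating log2 fold changes over genes, in the order 2,4-BPS with BPSIP, BPS and E2, BPSIP with BPS and E2, and BPS with E2. In females the correlations were 0.475, 0.428, 0.334, 0.277, 0.32 and 0.39. Comparisons that share their control correlate without any shared effect, and simulated data with no exposure effect gave mean correlations of 0.495 to 0.507. The covariances were 0.168, 0.112, 0.0984, 0.0927, 0.121 and 0.109, against simulated means of 0.0413 to 0.0424. In males the correlations were 0.692, 0.738, 0.716, 0.672, 0.654 and 0.686 (simulated 0.502 to 0.516) and the covariances 0.389 to 0.415 (simulated 0.0416 to 0.0429). In the same order 780, 604, 397, 632, 694 and 507 genes rose with both exposures in females (135 to 293 expected of independent calls), 669, 372, 311, 476, 642 and 302 fell with both (87.6 to 282 expected), and 330, 121, 442, 329, 494 and 241 went opposite ways. In males 1267 to 1711 rose with both, 1313 to 1810 fell with both and 174 to 384 went opposite ways. The 3 controls of a sex cannot be divided between exposures, so the part of this excess that comes from the controls was not separated, and genes are not independent of each other.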

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

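The tests of where the female transcripts, the clock shift and the small spread come from were chosen after these patterns were seen; the tests on other splits of the libraries were set beforehand. The results of this part are differences between the sexes in the effect of the same exposure, by the interaction test, with 2,4-BPS at 4919 genes, BPSIP at 5136, BPS at 4362 and E2 at 2389. For 2,4-BPS they include Hsd3b1 (12.24), Sult3a2 (9.66), Slc22a26 (9.43), Hspb1 (−5.50), H2bc8 (−4.08) and Tff3 (−4.00), as female minus male log2 fold changes. For BPSIP they include Sult2a5 (11.84), Cyp2b13 (10.53), Slc22a27 (9.70), Cfap53 (−8.35), Cyp4a14 (−6.37) and Fgf21 (−5.27). For BPS they include Sult3a2 (12.91), Sult3a1 (10.58), Cyp2b13 (10.30), Cyp4a12b (−7.48), Cib3 (−4.61) and Tff3 (−3.81). For E2 they include Sult3a1 (12.30), Cyp2b13 (11.51), Sult3a2 (11.10), Cyp4a12b (−8.26), Saa2 (−8.11) and Myom2 (−6.96). For Cfap53 and Tff3 both female groups lie under 0.101 CPM, so the female side was not measured. Hsd3b1 has no counts in 2,4-BPS males (at least 124-fold below control) and Sult2a5 none in BPSIP males (at least 394-fold). Slc22a27 with BPSIP, Sult3a2 with BPS and Cyp2b13 with E2 have 1 to 3 in males, as have Cib3 with BPS and Cyp4a12b with E2 in females. Their values above are not measured folds. Without female control library 3, Tff3 had −3.24 with an adjusted p of 0.0946 for 2,4-BPS and −3.04 with 0.131 for BPS.

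In 1 of 25 splits within sexes, the real one, as many genes were called for 2,4-BPS (next highest 3105), BPSIP (2574) and BPS (3785). For E2, 4 of 25 splits called at least 2389 genes, up to 3013. These splits mix exposed and control libraries and cannot test if effects differ by sex. Those with most calls kept 1 sex as it was, females for BPSIP and males otherwise, so its real contrast remained. In the joint tests 1 of 40 splits, the real one, called 8122 genes in females (next 769) and 8605 in males (next 168), and chance is excluded.

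For Sult2a5, Sult3a1, Sult3a2, Cyp2b13, Slc22a26 and Slc22a27 the male side of the difference is a fall against the libraries labelled male control, which hold female transcripts. Feminized liver transcription in male animals would leave Y-linked transcripts at the level of other males, but their sum was 0.582 of the mean of exposed male libraries, where single exposed males ranged from 0.863 to 1.11. A swap of labels with a female group would leave no Y-linked transcripts, and the lowest of the 3 libraries had 0.557. RNA of females mixed into these samples stays open. The missing Y-linked transcripts give a female share of 0.418, within the quartiles 0.342 to 0.624 of the ratio of female-specific transcripts. But the 6 male-specific genes outside the Y chromosome had a median of 0.736 of exposed males (quartiles 0.652 to 0.798) where this share predicts 0.582, and the only males to compare with are exposed. The X-linked genes Kdm6a, Kdm5c, Ddx3x and Eif2s3x were above every exposed male group (21.1, 74.4, 246 and 61.9 against at most 18.2, 69.1, 243 and 59.3 CPM), the direction female RNA would give. But Kdm6a and Kdm5c stand at the level of control females (21.2 and 73.2), beyond a share of 0.418. Female transcripts leave this share both ways: Sult2a1 had 35.2 against 499 CPM in control females, Sult2a3 0.114 against 18.6 and Cyp2a22 18.8 against 174, but Sult3a1 247 against 244, Sult3a2 39.5 against 44.8 and Cyp2b13 93.5 against 119. The mixed comparison rests on the share from Y-linked genes alone.

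Replicates were alike. The median standard deviation of log2 CPM within a group was 0.056 to 0.098, and Trim12a or Cfhr3 were on or off in whole groups of an outbred stock: in females Trim12a had 3.75 ± 0.738 CPM with 2,4-BPS and 0 with E2. Counting noise alone was exceeded in all 30 pairs of libraries of a group (chi-square over degrees of freedom 5.75 to 26.4). Libraries of a group made from shared RNA and separate livers cannot be told apart, since the lists disagree. Clock, immediate early and interferon genes together varied within groups at percentile 85.4 of random lists and between groups at percentile 100. Within groups, acute phase genes were at percentile 92.6, and male-biased (standard deviation 0.0901 against 0.0675 in random lists) and female-biased genes (0.258 against 0.091) at percentile 100. Female-biased genes such as Cyp2b13 are near 0 counts in exposed males, where counting error is large. The labels describe single livers, and animals alike for other reasons were not tested. If RNA was shared, the p values measure technical spread.

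Clock genes shifted in E2 females, 2,4-BPS males and E2 males. Genes that peak with Arntl minus genes that peak with Dbp differed by a log2 of 3.39, 3.34 and 3.96 there, and by −0.02 to 1.51 in the other 5 comparisons. The male values are against the libraries labelled male control, and in the mixed comparison they were 2.43 with 2,4-BPS and 2.68 with E2. Hour of tissue collection differing between groups predicts this, and so does an exposure effect on the clock; the smallest value, 3.34, cannot be told apart between them since no hour of collection is given.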

How the results depend on the processing

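The mixed comparison and the comparison of exposed groups with each other were chosen after the results were seen; the other alternatives were set beforehand. The numbers of genes called stayed within 1.5 times under DESeq2, RLE factors and no filter in 27 of 27 comparisons each, in 204 of 204 fits without a library, and in 8 of 8 with 6 libraries, all 30 libraries or log2 FPKM. Named genes kept direction and call in 376 of 376 cases with DESeq2, 375 of 376 with RLE factors and with the replicate block, 270 of 273 with 6 libraries and 2369 of 2400 without a library, and list calls in 144 of 145 with RLE factors, in 844 of 870 without a library, in 137 of 145 with fry and in 65 of 145 with an estimated correlation. Replicate numbers do not pair the samples: log2 values of the same number correlated at −0.0099 and of other numbers at 0.0053, each library went best with its own number in all 3 pairs in 2 of 20 comparisons, and with the replicate block 2554 genes were called for 2,4-BPS females and 5807 for BPS males, while no count moved beyond 1.5 times. On simulated data, folds of 1.5, 2 and 4 were recovered at 80, 88 and 98% in females, 70, 84 and 98% in males (at 1.5-fold 84% of raised and 56% of lowered genes) and 60, 76 and 98% for the female minus male difference, so changes of less than 1.5-fold are missed more often; the depth leaves genes under 0.101 CPM out of reach.

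Exposures here follow the order 2,4-BPS, BPSIP, BPS and E2, and the cause was not tested unless the setting itself makes calls fewer. At a log2 fold change of at least 1, counts were 299, 867, 262 and 356 in females and 796, 813, 726 and 779 in males. With an estimated correlation 7, 9, 6 and 6 lists were called in females and 10, 10, 8 and 9 in males; with fry, 29 in BPSIP males and 27 in E2 males. Correlations of log2 fold changes for the 6 pairs of exposures, in the order of the report, were 0.457, 0.497, 0.173, 0.37, 0.334 and 0.354 in females and 0.777, 0.854, 0.803, 0.788, 0.741 and 0.77 in males over genes above the median level. Leaving out a control library gave 0.53 to 0.565, 0.478 to 0.558, 0.408 to 0.487, 0.357 to 0.405, 0.388 to 0.431 and 0.428 to 0.506 in females, and 0.697 to 0.722, 0.738 to 0.76, 0.721 to 0.741, 0.669 to 0.694, 0.651 to 0.677 and 0.701 to 0.718 in males. The score difference turned to 0.0525 for 2,4-BPS and 0.106 for BPSIP females without multigene clusters, and to 0.0953 for BPSIP females on log2(FPKM + 1). In BPS and E2 females it shrank from −0.488 and −0.936 to −0.17 and −0.362 without clusters and to −0.277 and −0.573 on log2(FPKM + 1).

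Against the other exposed males, BPS had 12 list calls, the E2 difference between the sexes covered 4299 genes, and exposed females against exposed males gave 8246 genes, with 12 libraries per sex, where controls gave 4267 with 3. Of lists 29 of 72 kept call and direction, 18 lost the call and 25 turned. Of gene calls 36.7 to 52.3% were kept, and 383 to 524 turned. These lists turned direction there (adjusted p): for 2,4-BPS xenobiotic metabolism (0.121); for BPSIP male-biased (0.291), female-biased (5.26e-05), hormone receptor (0.668), xenobiotic (0.00256), glucose (0.291), antigen presentation (0.0385), endoplasmic reticulum stress (2.65e-12), heat shock (1.53e-05), macrophage (0.544), oxidative phosphorylation (0.297) and ribosomal (6.93e-05). For BPS they were female-biased (0.165), lipid synthesis (0.0653), clock (0.402), interferon (0.000105), endoplasmic reticulum stress (0.72), cell cycle (0.839) and macrophage (0.876), and for E2 male-biased (0.775), lipid synthesis (0.714), glucose (0.42), endoplasmic reticulum stress (0.0244), cell cycle (0.293) and macrophage (0.0338). The cause is in part the setting, since an effect shared by exposures cancels there.

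In the mixed comparison the male-biased list turned in the 4 exposures (0.0213, 1.83e-05, 0.000842 and 4e-05), and so did the female-biased list (0.12, 0.00613, 0.0607 and 0.0444), lymphocyte genes with 2,4-BPS (0.898) and endoplasmic reticulum stress with BPSIP (0.627). Genes that turned were Cyp7a1 (0.20), Cyp2b9 (0.31) and Cyp2c37 (0.56) with 2,4-BPS. With BPSIP they were Sult2a5 (0.51), Sult2a6 (0.73), Cyp3a16 (0.09), Pck1 (−0.02), Cyp2b9 (0.32) and Ccnd1 (0.41). They were Cyp2b9 (0.28) and Cyp2c37 (0.47) with BPS, and Cyp3a16 (0.11), Cyp2b9 (0.34), Cyp2c37 (0.52) and Cd74 (0.03) with E2. Of named genes 124 of 143 kept direction and call and 4 lost the call, and of lists 46 of 72 kept both and 16 lost the call.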

Other observations

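The mixed comparison was chosen after the results were seen, and the other tests of this part were set beforehand. Genes of secreted liver proteins, albumin among them, were higher by count in 2,4-BPS females (19 of 35 up and 1 down, 23 and 1 over the list alone, adjusted p = 2.46e-05, and 0.661 with an estimated correlation) and E2 females (17 of 35 up and 2 down, 21 and 4 over the list alone, adjusted p = 8.93e-07, and 0.416 with an estimated correlation), and lower by count in BPS males (24 of 35 down and 5 up, the same over the list alone, adjusted p = 0.00231, and 0.483 with an estimated correlation; mixed 27 and 2, 1.16e-06). Their summed level moved from 213000 ± 3530 CPM in control females to 247000 ± 14200 with 2,4-BPS and 240000 ± 8050 with E2, and from 231000 ± 4050 in the libraries labelled male control to 167000 ± 2390 with BPS, n = 3 per group. Bile acid genes were higher by count in E2 females (14 of 25 up and 3 down, the same over the list alone, adjusted p = 0.00124, and 0.429 with an estimated correlation) and BPSIP males (15 of 25 up and 4 down, the same over the list alone, adjusted p = 0.000263, and 0.16 with an estimated correlation; mixed 10 and 7, 0.00129), and lower by count in BPSIP females (13 of 25 down and 7 up, 14 and 8 over the list alone, adjusted p = 0.00451, and 0.465 with an estimated correlation).

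Imprinted and DNA methylation genes were not called as a list: 0, 3, 0 and 3 of 22 higher and 1, 4, 2 and 2 lower in females with 2,4-BPS, BPSIP, BPS and E2, 0, 3, 0 and 4 and 0, 4, 2 and 2 over the list alone (adjusted p = 0.875, 0.891, 0.828 and 0.873). Muscle genes were higher by count in 2,4-BPS females (8 of 13 up and 0 down, 9 and 0 over the list alone, adjusted p = 0.00341, and 0.636 with an estimated correlation; adjusted p = 0.0642 without 2,4-BPS library 1) and males (8 of 12 up and 0 down, the same over the list alone, adjusted p = 0.00502, and 0.303 with an estimated correlation; mixed 6 and 0 of 11 tested, 0.00966), but unevenly: Acta1 had 12.9, 4.35 and 2.3 CPM in the 3 females.

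With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Each real split of an exposure against control, of a pair of exposures and of the sexes among controls called more genes than the other 9, 1 of 10. Against control the highest others were 0, 0, 12 and 1 genes in females and 0, 17, 0 and 0 in males, for pairs of exposures 15, and for the sexes 0, beside real counts of 2333 to 5821, 2701 to 5455 and 4267. For gene lists with the preset correlation the real counts were 15, 19, 19 and 20 in females (highest others 17, 18, 19 and 16) and 17, 19, 21 and 15 in males (19, 15, 20 and 15). As many lists were called in 3, 1, 2 and 1 of 10 splits in females and 3, 1, 1 and 3 in males.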
